A study of Arabidopsis thaliana with 30 samples.

How the data were processed

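Gene expression was measured on 30 Affymetrix ATH1 arrays of Arabidopsis root tissue in 8 groups. Per the labels, the tissue of at least 25 seedlings was pooled for each replicate and 50 ng of total RNA was amplified and labelled by the two-cycle protocol. The authors deposited 1 MAS5 signal per probe set and array, on a linear scale. The version of MAS5 is not given in the sources used here. The 2% trimmed means of the arrays spanned 246.5 to 248.6, a spread of 0.863%, so the signals were taken as already scaled and were not scaled again. The scanner information files hold no measurement and empty date fields, and were not used here. Pools average over seedlings, so the spread between replicates does not show the spread between plants.

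Signals were transformed as log2(signal + 32), where the pseudocount of 32 shrinks differences between dim probe sets. All arrays entered 1 linear model with a coefficient per group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with trend=TRUE), with Benjamini-Hochberg adjustment over 22746 probe sets. A probe set counted as changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. There were 12 comparisons, of which 6 use the stump arrays at 0 h in a simple difference and share their error. Plots were drawn with matplotlib 3.10.9. In simulated data with 2-, 4- and 8-fold changes, the model recovered 34.3%, 98.5% and 98.5% of changed probe sets for the tip against the stump at 0 h (22746 probe sets, 11 false calls). It recovered 31.3%, 94% and 100% for 22 h against 0 h (2 false calls) and 20.9%, 77.6% and 98.5% for the tip against the stump at 8 dpg (8 false calls). Changes were set only in probe sets with a mean above the median, and the noise was independent, normal and equally wide in all groups. These rates therefore do not cover dim probe sets or groups of unequal spread.

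Probe sets were named through a table that pairs them with genes: 14016 were listed, 13513 with 1 gene and 503 with several, and 8730 were not listed. Of those with 1 gene, 13436 matched the RefSeq annotation by gene ID (assembly TAIR10.1, used for names only), and they stood for 13355 different genes. The groups, the tests, 18 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The lists held 241 different genes, of which 33 had a named probe set, and 2 lists reached the 4 members needed for a test. A further 20 lists were drawn up once it was known which probe sets carry a name, so 22 were tested, with camera at a preset correlation of 0.01, with an estimated correlation beside it, and with adjustment over the lists within a comparison. A list's median, mean and test differed in sign in 55 of 264 pairs of list and comparison, of which 0 were called.

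The rule allows up to 10 risen and 10 fallen genes per comparison with the largest change among those called, whose replicates do not overlap between the groups, whose higher group lies above the median of all probe sets and whose probe set has 1 gene. It adds up to 4 members of each list with the smallest p, and every member of the stem cell niche list. The condition on overlap favours genes with a small spread. The rule gave 1440 pairs of gene and comparison, 407 of them with an adjusted p under 0.05, and 219 pairs, 197 of them with such a p, were picked from these for the text after their values were seen. A selection of 163 pairs that left out genes whose calls were lost when 1 array was omitted was tried and dropped, because it selects for stability. When 1 array was omitted, the adjusted p rose above 0.05 in 18.9% of tests of these genes over the whole rule, in 10.1% over the text's genes and in 1.36% over the dropped selection. The text's genes are therefore more stable than those the rule gives.

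The score of tip expression is the mean log2 value of tip-high probe sets minus that of the others in the signature, tested by two-sided exact permutation. The planned signature, from the tip and the stump at 8 dpg, had 0 members. A score from split arrays parted the 4 stump arrays at 0 h in every way, 6 in all, and a signature from the tip at 8 dpg against the section was added after the data were seen. The share of tip-high probe sets that rose was compared with 20 simulations without effects that kept the shared 0 h arrays, and with the same 6 splits.

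Alternatives were a pseudocount of 1, a larger pseudocount, quantile normalization, median centring, leaving out the 40% dimmest probe sets, trend=FALSE, a fit of only the groups compared, a replicate block, each array left out in turn and, for lists, fry. Chosen after the data were seen were array weights and leaving out 2 arrays of low correlation or the 4 arrays with a median signal above 120.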

Results

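The series followed the root of Arabidopsis thaliana (accession Col-0) after its tip was cut away. The protocol gives lengths in µm, used here, where the sample titles print mm. Seedlings were grown for 4 days, the distal 130 µm was excised, and the 70 µm next to the cut, called the stump here, was collected at 0, 5, 13 and 22 h after excision. The excised tips of seedlings at 4 and 8 days post germination (dpg), a stump at 8 dpg and a section labelled 270 to 340 from the root tip were also collected. The design text names the tips as the endpoint of regeneration and the section as wounded tissue that does not regenerate. The titles of the section say that it was harvested immediately, so it is not matched in time to the stumps at 5, 13 and 22 h. The labels state the stump at 8 dpg in conflicting ways, as recut at 0 h in the title and as 192 h after the first cut in the source name, and they give no age for the section. Each replicate pooled at least 25 pieces of tissue, and RNA was hybridised to ATH1 arrays. The 30 arrays comprised 4 each of the tip at 4 dpg and the stump at 0, 5 and 13 h, 5 of the stump at 22 h, and 3 each of the tip at 8 dpg, the stump at 8 dpg and the section. The labels do not say whether replicates came from separate sowings, so p-values measure only the spread between these arrays.

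Each array held 22746 probe sets, and the number of arrays limits the precision. The 2% trimmed mean signals lay between 246.5 and 248.6, but medians ran from 66.1 to 141.8. The medians of 4 arrays stood above 120: 141.8 and 121.3 in stump 0 h arrays 1 and 2, 126.65 in tip 4 dpg array 1 and 122.6 in stump 22 h array 1. Correlations of log2 values between arrays of a group were 0.793 to 0.929 at stump 0 h and 0.821 to 0.934 at 22 h. They were 0.918 to 0.945 at 5 h, 0.974 to 0.976 for the tip at 8 dpg and 0.96 to 0.967 for the section. No pair of arrays held the same values, and the closest pair had r = 0.976. Of the probe sets, 13513 carried 1 gene name, 503 carried several and 8730 were unnamed here. Differences are given on the log2(signal + 32) scale, which understates changes of dim genes, and as the first group minus the second.

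**Figure D1:**
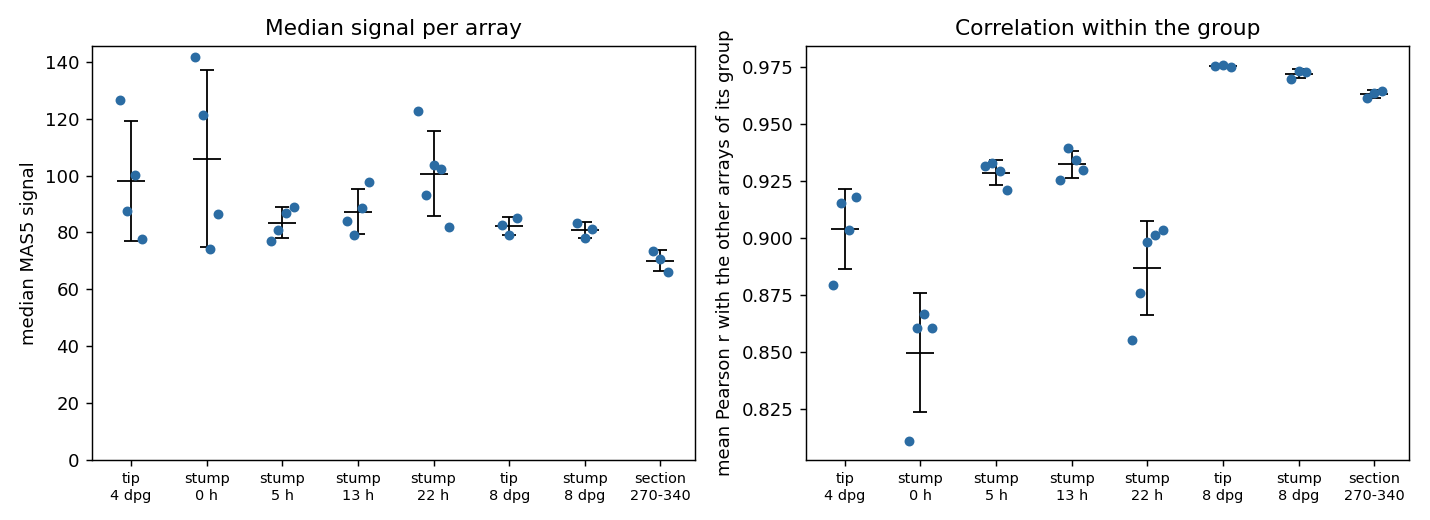
Each point is 1 array, grouped by tissue on the horizontal axis, with the median MAS5 signal in 1 panel and the mean Pearson r with the other arrays of its group in the other, and bars for the group mean ± SD. Stump 0 h array 1 had the highest median, 141.8, and the lowest mean correlation, 0.811.

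**Figure D2:**
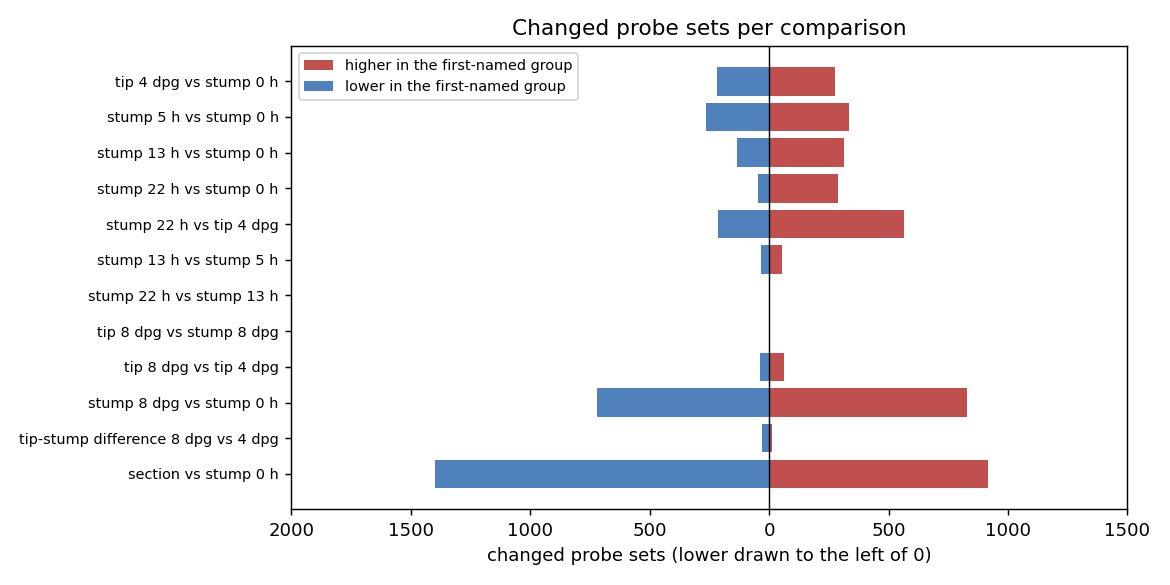
Bars give the number of changed probe sets in each comparison, with those higher in the first-named group to the right of 0 and those lower to the left. The section against the stump at 0 h had 917 higher and 1401 lower, and the tip against the stump at 8 dpg had 0.

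The tip at 4 dpg was compared with the stump at 0 h (4 arrays each) to find what the removed tissue expressed and the fresh stump did not. Among named genes, AT1G50060, of the PR-1-like family, was higher in the tip by 4.38 ± 0.54 (log2, SE; adjusted p = 6.36e-06). Its signals were 1500 ± 698 and 61.9 ± 101 (SD). The metallothionein gene MT1C (AT1G07610) was higher by 3.98 ± 0.753, the jacalin-type lectin gene AT1G52070 by 2.98 ± 0.427 and the LEA-related genes AT5G60530 and AT5G60520 by 2.62 ± 0.461 and 2.6 ± 0.277. AT3G19430 (3.89 ± 0.457), the GH3-family genes AT1G23160 (2.55 ± 0.445) and AT5G51470 (2.56 ± 0.434) and scpl48 (2.46 ± 0.36) were also higher in the tip. Lower in the tip were the peroxidase gene AT4G30170 (-3.25 ± 0.637), SIM (-3.03 ± 0.503) and the beta-tubulin genes TUB1 (-2.81 ± 0.415) and TUB5 (-1.29 ± 0.335). SIM encodes an inhibitor of cyclin-dependent kinases that promotes endoreduplication. AT1G62480 (-3.61 ± 0.575), the acid phosphatase gene AT1G04040 (-3.14 ± 0.578), AT1G67330 (-3.11 ± 0.446), the vacuolar invertase gene AT1G62660 (-2.74 ± 0.415), and AT5G44020 (-2.68 ± 0.563) were lower as well. So were the defensin gene LCR68 (-2.66 ± 0.5), AT1G57590 (-2.61 ± 0.331) and XTH16 (-2.14 ± 0.375). EXPA20, an expansin gene, was higher by 1.22 ± 0.261 and the dehydrin gene COR47 by 2.13 ± 0.568. The 20 ribosome biogenesis genes all had positive differences, with a median of 0.496, but 0 passed singly. For the list camera gave adjusted p = 5.09e-05, and adjusted p = 0.6 with an estimated correlation. The RNA polymerase I gene NRPA2 in that list differed by 0.954 ± 0.243 (adjusted p = 0.025), under the size threshold. Of 69 plastid-encoded genes 0 were called, and the list's shift of 0.181 had adjusted p = 0.0168, and adjusted p = 0.75 with an estimated correlation. Neither planned list with enough named members shifted: of 8 auxin response genes and 5 wound and ethylene regulators 0 passed, and adjusted over the list alone 0 and 1 did.

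In all, 494 probe sets changed between the tip and the stump, 274 higher in the tip and 220 lower. The count was 989 without tip array 1, 281 without tip array 3, 326 without tip array 4, 302 without stump array 2, 961 without stump array 4 and 54 when only these groups entered the fit. COR47 lost its call without tip array 1, 2 or 4 or stump array 1 or 4 (at most adjusted p = 0.111, log2 1.95), and TUB5 without tip array 3 or 4 or stump array 2 or 3 (0.157, -0.984). NRPA2 had an adjusted p above 0.05 without tip array 2, 3 or 4 or stump array 2 or 3 (at most 0.116, log2 0.8). COR47 also lost its call with trend=FALSE, array weights and without the arrays of high median (at most adjusted p = 0.0712), TUB5 with median centring (0.105), and NRPA2 passed neither with array weights (0.0957) nor without the 4 arrays of high median (0.158). With only these groups in the fit AT1G04040 (0.0791), EXPA20 (0.372), XTH16 (0.204), COR47 (0.0998), TUB5 (0.442) and NRPA2 (0.351) did not pass. EXPA20 fell below the size threshold with the larger pseudocount (log2 0.603).

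At 5 h (4 arrays against 4), the largest rise was that of AT5G22580, a stress-responsive A/B barrel gene, by 6.42 ± 0.324 (log2, SE; adjusted p = 1.34e-15), from a signal of 103 ± 88 to 9710 ± 1070 (SD). The protease inhibitor gene AT2G38870 rose by 4.3 ± 0.423, the dehydrin gene AT4G38410 by 3.99 ± 0.393, the VQ-motif gene AT2G22880 by 3.71 ± 0.407, and AT4G30650, of a low-temperature and salt responsive family, by 3.7 ± 0.495. The chitinase-family gene AT2G43620 (3.66 ± 0.446), the leucine-rich repeat gene AT2G34930 (3.63 ± 0.396), the expansin-like genes EXLA1 (3.4 ± 0.494) and EXLA2 (3 ± 0.338) rose. So did the peroxidase gene AT5G39580 (3.34 ± 0.415) and the dehydrin gene LTI30 (2.4 ± 0.503). Of the 5 wound and ethylene regulators with a named probe set, 2 rose: AT5G61890, an ERF-family transcription factor (3.38 ± 0.443), and the zinc-finger factor STZ (1.83 ± 0.362); adjusted over the list alone the count was also 2. This list shifted up by a median of 0.924 (camera adjusted p = 5.07e-06), with adjusted p = 0.000994 with an estimated correlation. Of 19 heat shock and chaperone genes 5 rose and 1 fell, among them Hsp70-2 (2.56 ± 0.369) and AT1G54050 (2.32 ± 0.435). The list had adjusted p = 4.55e-08, and adjusted p = 0.0739 with an estimated correlation. The auxin-conjugating enzyme gene GH3.3 rose by 1.86 ± 0.466, the 1 gene of 8 auxin response genes called, also 1 when adjusted over the list alone. Of 15 nuclear photosynthesis genes 2 fell, the chlorophyll synthesis gene CHLM (-1.43 ± 0.253) and ATPC1 (-1.24 ± 0.317), with adjusted p = 0.00407 for the list, and adjusted p = 0.285 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.269 over 107 members, 0 called, with adjusted p = 1.24e-08, and adjusted p = 0.397 with an estimated correlation. AT2G42110 (-2.04 ± 0.42), AT1G78260 (-1.91 ± 0.424), the aspartyl protease gene AT1G09750 (-1.85 ± 0.396) and AT3G49190 (-1.71 ± 0.438) fell, and the Aurora kinase gene AUR2 differed by -0.946 ± 0.251 (adjusted p = 0.03), under the size threshold.

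In this comparison 599 probe sets changed, 336 higher and 263 lower at 5 h, so 56.1% were higher, against 74.7% with quantile normalization and 87.5% with median centring. The median of all probe sets was -0.147, and centring moved it to 0.0841. The count was 373 without stump 0 h array 1, 1078 without its array 3, 1030 without its array 4, 344 and 395 without 5 h arrays 3 and 4, and 139 with only these groups in the fit. ATPC1 lost its call without stump 0 h array 1 or 5 h array 3 or 4 (at most adjusted p = 0.0991, log2 -1.08), AT3G49190 without stump 0 h array 3 or 5 h array 1 or 3 (0.0864, -1.57), and GH3.3 without 5 h array 3 or 4 (0.0708, 1.74). AUR2 passed the adjusted p neither without stump 0 h array 1 nor without 5 h array 1 or 2 (at most 0.124, log2 -0.787). With quantile normalization ATPC1 (adjusted p = 0.0963), AT3G49190 (0.0537) and AUR2 (0.108) did not pass, nor with centring (0.102, 0.0795 and 0.164) or array weights (0.115, 0.0786 and 0.0758). GH3.3 was lost with the smaller pseudocount (0.0513), AT1G78260 with array weights (0.0761), and AT1G78260 (0.115) and AT1G09750 (0.0567) without the 4 arrays of high median. Only these groups in the fit ended the calls of AT2G42110 (0.103), AT1G78260 (0.096), GH3.3 (0.103), CHLM (0.124) and ATPC1 (0.256), and AUR2 had 0.312. The larger pseudocount put AT1G78260 (log2 -0.991), CHLM (-0.894) and ATPC1 (-0.774) below the size threshold.

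By 13 h (4 arrays against 4), AT2G38870 was higher than at 0 h by 5.26 ± 0.423 (log2, SE; adjusted p = 2.25e-10) and AT5G22580 by 5.25 ± 0.324. The chitinase-family gene AT2G43620 rose by 4.24 ± 0.446, the defensin gene LCR69 by 4.19 ± 0.437. So did the peroxidase genes AT5G64120 and AT5G64100 by 3.67 ± 0.538 and 2.96 ± 0.561, the pectate lyase gene AT3G27400 by 3.46 ± 0.398 and the Aux/IAA gene IAA33 by 3.09 ± 0.297. Of 19 expansin genes 3 rose, EXPA8 (2.24 ± 0.436), EXPA20 (2.02 ± 0.261) and EXPA4 (1.81 ± 0.331), with adjusted p = 0.000997, and adjusted p = 0.117 with an estimated correlation. Of 10 xyloglucan endotransglucosylase genes 2 rose, XTH19 (1.57 ± 0.41) and EXGT-A3 (1.35 ± 0.264), with adjusted p = 0.000997, and adjusted p = 0.189 with an estimated correlation. The immune kinase gene BIK1 (1.8 ± 0.268), the ubiquitin ligase gene PUB22 (1.54 ± 0.267), Hsp70-2 (2.38 ± 0.369) and AT5G61890 (2.26 ± 0.443) rose. AT5G61890 was the 1 member of 5 wound and ethylene regulators called, also 1 when adjusted over the list alone. Of 8 auxin response genes 0 were called over all probe sets, and 1 higher and 1 lower when adjusted over the list alone. The heat shock list had 3 of 19 genes higher (adjusted p = 6.35e-06), with adjusted p = 0.117 with an estimated correlation. The plastid-encoded genes had a median of -0.4, 1 of 69 lower, with adjusted p = 0.000997, and adjusted p = 0.688 with an estimated correlation. Root hair and extensin genes had adjusted p = 0.0454 with 0 of 14 called, and adjusted p = 0.688 with an estimated correlation. With quantile normalization it was 0.0879 and with centring 0.0883. The aldehyde dehydrogenase gene ALDH3F1 (-1.92 ± 0.368), AT3G49190 (-1.89 ± 0.438), AT2G45180 (-1.76 ± 0.353), the defensin gene PDF2.5 (-1.76 ± 0.459) and the ribosomal S25 gene AT4G39200 (-1.66 ± 0.355) fell. Of the 450 probe sets changed at 13 h, 314 were higher and 136 lower, 69.8% higher against 85.8% with median centring. The count was 773 without stump 0 h array 3, 842 without its array 4 and 166 with only these groups in the fit. XTH19 lost its call without stump 0 h array 1 or 13 h array 1, 2 or 4 (at most adjusted p = 0.182, log2 1.14), PDF2.5 without stump 0 h array 1 or 13 h array 3 or 4 (0.199, -1.12), and AT3G49190 without 13 h array 1 or 4 (0.0626, -1.69). With array weights XTH19 (0.171), PDF2.5 (0.102), AT4G39200 (0.0596) and AT3G49190 (0.0659) were not called, and without the 4 arrays of high median neither were XTH19 (0.137), PDF2.5 (0.0676) and AT4G39200 (0.11). XTH19 was also lost with the smaller pseudocount (0.0986) and PDF2.5 with trend=FALSE (0.0516). Only these groups in the fit ended the calls of ALDH3F1 (0.0541), PDF2.5 (0.154), AT4G39200 (0.17), AT5G61890 (0.0522), EXGT-A3 (0.0536) and XTH19 (0.132).

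From 5 h to 13 h (4 arrays each), AT5G64100 rose by 4.01 ± 0.561 (log2, SE; adjusted p = 0.000153), AT3G27400 by 2.9 ± 0.398, EXPA8 by 2.81 ± 0.436 and the peroxidase gene AT5G17820 by 2.94 ± 0.62. AT2G32190 (-3.21 ± 0.29), AT4G22212 (-2.18 ± 0.301), EXLA1 (-2.8 ± 0.494) and EXLA2 (-2.21 ± 0.338) fell. Nuclear photosynthesis genes shifted up, 15 of 15 with positive differences and 1 called, ATPC1 (1.6 ± 0.317), with adjusted p = 3.56e-09, and adjusted p = 0.0106 with an estimated correlation. The 5 wound and ethylene regulators shifted down with 0 called, adjusted p = 0.000959, and adjusted p = 0.013 with an estimated correlation; adjusted over the list alone 2 were lower. Cytosolic ribosomal protein genes had a median of -0.329 with 0 of 107 called, adjusted p = 6.29e-16, and adjusted p = 0.126 with an estimated correlation. AUR2 rose by 1.2 ± 0.251 and JAL33, of the ER body list, by 1.18 ± 0.258. In all 85 probe sets changed, 52 higher and 33 lower, 61.2% higher against 46.4% with median centring. The count was 53, 38 and 41 without 5 h arrays 2, 3 and 4, and 43, 48 and 51 without 13 h arrays 2, 3 and 4. Calls lost without single arrays were those of AT5G17820 (5 h array 1, 2 or 3, 13 h array 1 or 2; at most adjusted p = 0.137, log2 2.42) and ATPC1 (5 h array 3 or 4, 13 h array 3; 0.0825, 1.44). So were those of AUR2 (5 h array 2, 13 h array 2, 3 or 4; 0.106, 1.02) and JAL33 (any of arrays 2, 3 and 4 at either time; 0.14, 1.1). AUR2 also lost its call with quantile normalization (0.0512) and centring (0.0683), JAL33 with centring (0.203) and trend=FALSE (0.0525), EXLA2 with the smaller pseudocount (0.0656) and AT5G17820 with the larger (0.106). The larger pseudocount put AUR2 below the size threshold (log2 0.853).

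**Figure D3:**
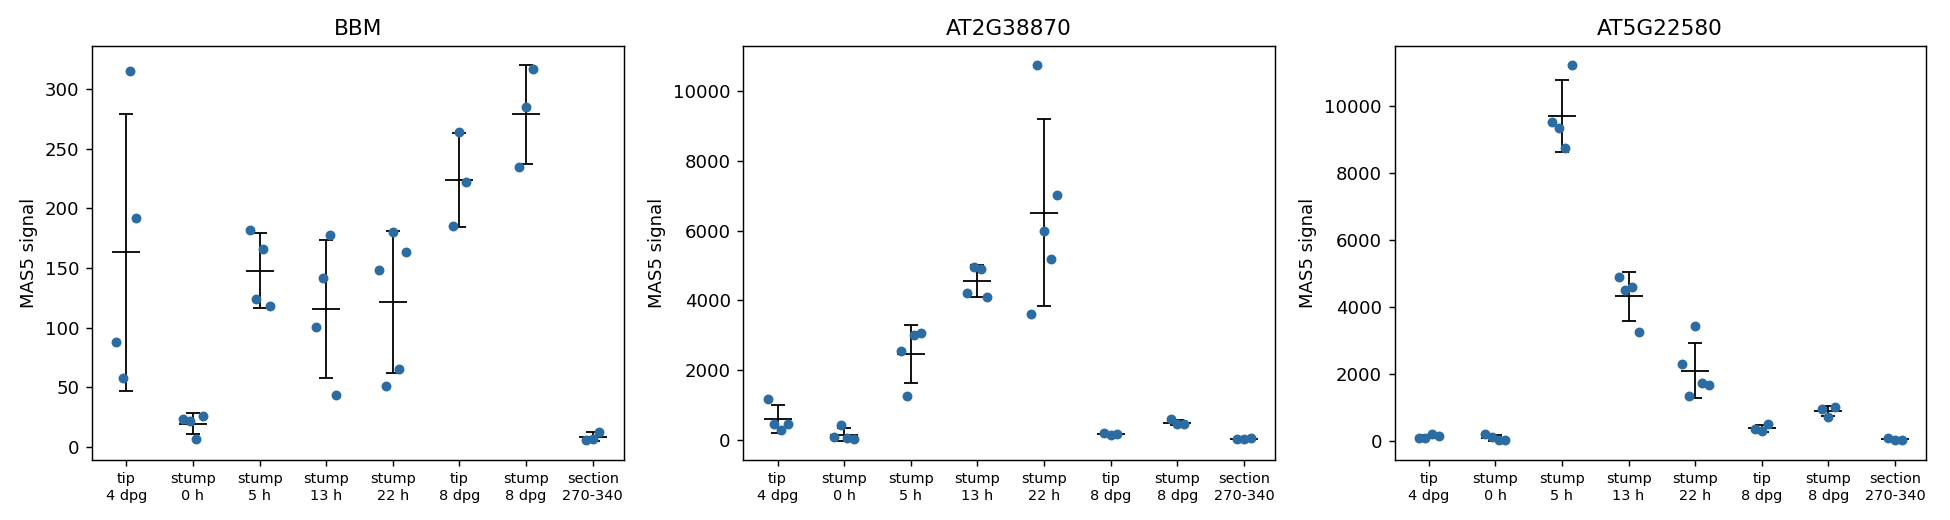
MAS5 signal of BBM, AT2G38870 and AT5G22580 in each array (points) with the group mean ± SD (bars), over the 8 groups on the horizontal axis. AT5G22580 had a mean of 9710 at 5 h and 2110 at 22 h, and AT2G38870 a mean of 2460 at 5 h and 6520 at 22 h.

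At 22 h (5 arrays against 4), AT2G38870 was higher than at 0 h by 5.69 ± 0.401 (log2, SE; adjusted p = 1.41e-11), AT5G22580 by 4.17 ± 0.308, MT1C by 4.09 ± 0.715, LCR69 by 3.96 ± 0.414, IAA33 by 3.12 ± 0.282 and AT2G43620 by 2.75 ± 0.423. Of 51 class III peroxidase genes 6 rose and 0 fell, among them AT4G36430 (3.1 ± 0.556) and AT5G64100 (2.81 ± 0.532). AT5G64100 stood at 3890.8 and 2240.3 in 22 h arrays 2 and 3, the arrays with the lowest tip-minus-section scores (-0.758 and -0.385), and at 434.9, 482.5 and 544.8 in the others. The peroxidase list had adjusted p = 0.000801, and adjusted p = 0.22 with an estimated correlation. Of 19 expansin genes 3 rose, EXPA20 by 2.07 ± 0.248, with adjusted p = 0.00475, and adjusted p = 0.19 with an estimated correlation. Of 11 autophagy genes 1 rose, ATG8E (1.73 ± 0.428), with adjusted p = 0.00215, and adjusted p = 0.19 with an estimated correlation. COR47 (2.63 ± 0.539), the lipocalin gene TIL (1.32 ± 0.295), BIK1 (1.69 ± 0.254), Hsp70-2 (2.13 ± 0.35), AT1G30870 of the root hair list (2.52 ± 0.635) and AT5G61890 (1.58 ± 0.42) rose. AT5G61890 was the 1 of 5 wound and ethylene regulators called, also 1 when adjusted over the list alone. AT5G62330 (-2.75 ± 0.297), AT3G49190 (-2.59 ± 0.415), the cis-prenyltransferase gene AT5G58784 (-1.89 ± 0.367), AT1G09750 (-1.45 ± 0.375), TUB5 (-1.21 ± 0.318) and the bHLH factor ATMYC1 (-1.12 ± 0.211) fell. Of the 335 changed probe sets 290 were higher and 45 lower, 86.6% higher. The count was 549 without 22 h array 1, 213 without 22 h array 3, 670 without the 4 arrays of high median and 77 with only these groups in the fit. Calls lost without single arrays were those of AT1G09750 (stump 0 h array 1 or 2, 22 h array 2 or 5; at most adjusted p = 0.181, log2 -1.11), AT1G30870 (0 h array 2, 3 or 4, 22 h array 2 or 3; 0.132, 2.06), AT5G61890 (0 h array 2, 3 or 4, 22 h array 1, 2 or 3; 0.198, 1.21). So were those of ATG8E (0 h array 1, 22 h array 2 or 3; 0.107, 1.5), TIL (0 h array 3 or 4, 22 h array 3; 0.0621, 1.13) and TUB5 (0 h array 2, 3 or 4, any 22 h array except 2; 0.182, -0.886). TUB5 also lost its call with quantile normalization (0.0514), centring (0.124) and trend=FALSE (0.0642). With array weights AT1G09750 (0.243), AT5G61890 (0.0593), AT1G30870 (0.156) and ATG8E (0.158) were lost. So were, with the smaller pseudocount, AT1G09750 (0.0959) and AT5G61890 (0.0619), with the larger AT5G61890 (0.0769) and AT1G30870 (0.068), and without the 4 arrays of high median AT1G09750 (0.261) and AT1G30870 (0.0541). With only these groups in the fit AT5G64100 (0.0701), AT5G58784 (0.167), AT1G09750 (0.203), ATMYC1 (0.181), AT5G61890 (0.55) and AT1G30870 (0.349) were lost. So were TIL (0.312), Hsp70-2 (0.0514), ATG8E (0.391) and TUB5 (0.494). ATMYC1 fell below the size threshold with the larger pseudocount (log2 -0.887) and without stump 0 h array 1 and 22 h array 1 (-0.996). Of 8 auxin response genes 0 were called, also when adjusted over the list alone.

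From 13 h to 22 h, 4 probe sets changed by the limma test and 1454 had an unadjusted p below 0.05. Of those with 1 gene name, AT3G23880 rose by 1.69 ± 0.25 (log2, SE; adjusted p = 0.0023), and AT5G62330 (-1.68 ± 0.297) and the methionine sulfoxide reductase gene MSRB9 (-1.22 ± 0.227) fell. The 2 higher and 2 lower make 50% higher, against 33.3% of 3 with quantile normalization. The count was 2 and 1 without 13 h arrays 2 and 3, 1, 10 and 8 without 22 h arrays 1, 2 and 5, 1 with centring or the larger pseudocount, and 0 with only these groups in the fit. AT5G62330 lost its call without 13 h array 1, 2 or 3 or 22 h array 1 or 4 (at most adjusted p = 0.108, log2 -1.49), and MSRB9 without any 13 h array or 22 h array 1, 3 or 4 (0.186, -1.11). Both were lost with the larger pseudocount (0.0855 and 0.0513) and with centring (0.0665 and 0.127), and MSRB9 with trend=FALSE (0.0972). With only these groups in the fit AT3G23880 (0.0546), AT5G62330 (0.757) and MSRB9 (0.477) were lost. The 11 autophagy genes all had positive differences with 0 called (adjusted p = 0.0018), with adjusted p = 0.313 with an estimated correlation. Of 8 auxin response genes and 5 wound and ethylene regulators 0 were called, and 1 and 0 when adjusted over the list alone.

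Against the tip at 4 dpg, the stump at 22 h (5 arrays against 4) had higher signals of the defensin genes LCR68 and LCR69, by 4.53 ± 0.474 (log2, SE; adjusted p = 8.95e-08) and 4.42 ± 0.414. LCR68 stood at 4194.7 and 2581.9 in 22 h arrays 2 and 3 and at 779.2, 788.4 and 496.5 in the others. AT1G04040 (3.95 ± 0.548), AT5G22580 (3.55 ± 0.308), AT2G38870 (3.51 ± 0.401), AT1G67330 (3.45 ± 0.423), LTI30 (2.22 ± 0.478) and TUB1 (1.93 ± 0.394) were also higher. Of 51 peroxidase genes 16 were higher and 2 lower, AT2G37130 by 3.72 ± 0.691 and AT5G64100 by 3.09 ± 0.532, with adjusted p = 3.16e-08, and adjusted p = 0.12 with an estimated correlation. EXPA8 (2.95 ± 0.414) was 1 of 2 expansin genes and XTH16 (1.85 ± 0.356) 1 of 2 xyloglucan endotransglucosylase genes called higher. The lists had adjusted p = 0.000476 and 0.000516, and adjusted p = 0.12 and 0.139 with an estimated correlation. Lower at 22 h were AT1G50060 (-3.72 ± 0.512), AT3G19430 (-3.22 ± 0.433), the lectin genes AT1G52050 (-3.1 ± 0.427), AT1G52070 (-2.75 ± 0.405) and AT1G52060 (-2.69 ± 0.442). So were AT5G60530 (-2.72 ± 0.437), the polygalacturonase gene AT1G65570 (-2.54 ± 0.369) and ATGSTF13 (-2.46 ± 0.489). Of 20 ribosome biogenesis genes 3 were lower, NRPA2 by -1.05 ± 0.231, with adjusted p = 3.98e-07, and adjusted p = 0.139 with an estimated correlation. In each of the planned lists of auxin response (8 genes) and wound and ethylene regulators (5 genes) 1 was higher, and the same number when adjusted over the list alone. In all 780 probe sets differed, 564 higher and 216 lower. The count was 500 without tip array 3, 497 without 22 h array 3, 1481 without the 4 arrays of high median and 274 with only these groups in the fit. That fit ended the calls of NRPA2 (adjusted p = 0.0608), XTH16 (0.053) and LTI30 (0.0749). NRPA2 (log2 -0.96) and XTH16 (0.984) fell below the size threshold with the larger pseudocount, and NRPA2 without 22 h array 2 (-0.826).

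The title of the series concerns stem cell niche activity, and 3 of the 11 planned niche and root patterning genes had a named probe set. BBM (AT5G17430), an AP2-type transcription factor of the PLETHORA family, had signals of 163 ± 117 in the tip at 4 dpg and 19.3 ± 8.6 in the stump at 0 h (SD, 4 arrays each). It stood at 148 ± 31.3 at 5 h, 116 ± 58 at 13 h and 122 ± 59.4 at 22 h, and at 8.37 ± 3.61 in the section. Against the stump at 0 h, BBM was higher by 1.74 ± 0.365 in the tip (log2, SE; adjusted p = 0.00497), 1.81 ± 0.365 at 5 h (0.00314), 1.44 ± 0.365 at 13 h (0.0259), 1.5 ± 0.346 at 22 h (0.015) and 2.61 ± 0.394 in the stump at 8 dpg (2.02e-05). At 22 h it differed from the tip by -0.246 ± 0.346 (adjusted p = 0.803). The zinc-finger gene JKD (AT5G03150) and the MADS-box gene AGL42 (AT5G62165) passed in 0 comparisons over all probe sets. JKD had signals of 92.6 ± 60.9 in the tip, 132 ± 100 at 0 h, 32.6 ± 38.5 at 5 h, 90.4 ± 27 at 13 h and 116 ± 88.1 at 22 h. AGL42 had 85.6 ± 35.3 in the tip, 96.5 ± 89.1 at 0 h and 134 ± 46.5 at 22 h. Adjusted over the list alone, BBM was called in the same 5 comparisons and in the interaction of tip-stump difference and age (-2.03 ± 0.558). JKD was then lower at 5 h (-1.32 ± 0.434), and AGL42 higher in the stump at 8 dpg than at 0 h (1.17 ± 0.441) and in the tip at 8 than at 4 dpg (1.12 ± 0.441). BBM lost its call at 13 h without stump 0 h array 3 or 13 h array 1, 2 or 3 (at most adjusted p = 0.113, log2 1.24) and at 22 h without stump 0 h array 3 or 22 h array 3 (0.0627, 1.36). With the larger pseudocount the differences were 0.696 (adjusted p = 0.0857) and 0.727 (0.0649), and with array weights BBM at 22 h had adjusted p = 0.0707. With only the compared groups in the fit BBM was not called in the tip at 4 dpg (adjusted p = 0.225), at 13 h (0.177) or at 22 h (0.231). With the larger pseudocount it was below the size threshold in the tip (log2 0.899) and at 5 h (0.899).

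The return of tip expression was to be scored on probe sets that differed between tip and stump at 8 dpg, but that set was empty. The score from split arrays used probe sets changed between the tip at 4 dpg and 2 of the stump 0 h arrays, against the other 2, over 6 splits. The stump at 22 h lay above the held-out 0 h arrays by a mean of 0.39 (log2; -0.518 to 0.802), above 0 in 5 of 6 splits, with two-sided exact permutation p from 0.0952 to 0.857. The value of -0.518 came from the split that chose probe sets on 0 h arrays 1 and 2, both of high median. The mean over all splits was 0.219 without 22 h array 5. In the same splits the mean was 0.166 at 5 h (-0.197 to 0.699) and 0.124 at 13 h (-0.229 to 0.592), each above 0 in 3 of 6. It was 2.43 for the stump at 8 dpg (0.744 to 3.5) and -1.5 for the section (-2.26 to -0.725). The tip's own value of 1.95 is fixed in part by the choice of probe sets, which used the same tip arrays. A further score, chosen after the data were seen, took 2258 probe sets higher and 1668 lower in the tip at 8 dpg than in the section. Its means were 0.819 ± 0.205 (SD, n = 4 arrays) in the tip at 4 dpg, -0.304 ± 0.38 at 0 h, -0.105 ± 0.0844 at 5 h, -0.331 ± 0.408 at 13 h and -0.0923 ± 0.467 (n = 5) at 22 h. The 22 h arrays exceeded those at 0 h by 0.212 (exact permutation p = 0.5, Benjamini-Hochberg 0.6 over 6 comparisons) and the tip at 4 dpg by -0.911 (exact permutation p = 0.0159, adjusted 0.0572), 5 of 5 arrays lying below every tip array. Without stump 0 h array 1 or 2 the difference of 0.212 was 0.362 or 0.0513. Without 22 h array 1, 2 or 5 it was 0.104, 0.373 or 0.104, and without the 4 arrays of high median 0.0941.

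**Figure D4:**
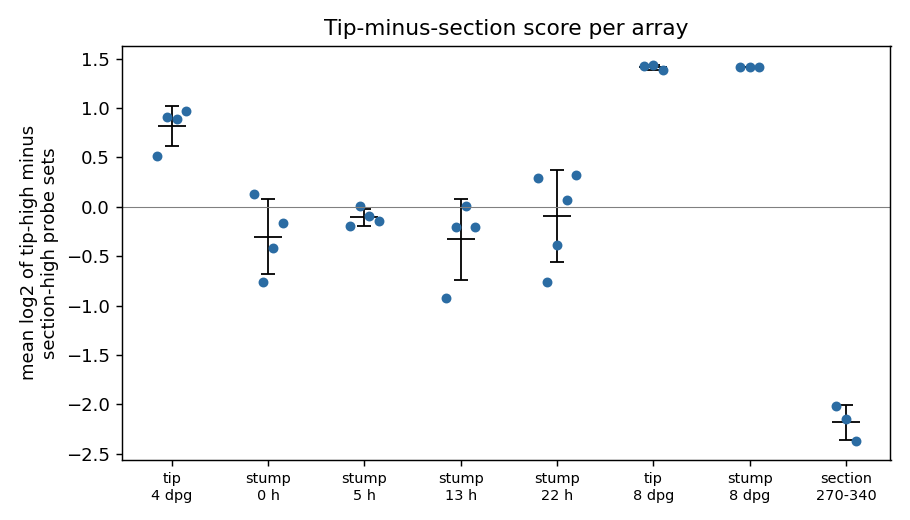
The tip-minus-section score, the mean log2 value of tip-high minus that of section-high probe sets, for each array (points) with the group mean ± SD (bars), where the tip at 8 dpg and the section define the score. The stump arrays at 22 h spread from -0.758 to 0.326.

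Of the 274 probe sets higher in the tip at 4 dpg, 68 rose in the stump by 22 h (24.8%), and 18 of the 220 lower ones fell. Both contrasts use the same 0 h arrays. Simulated arrays without effects, in which the contrasts also shared a 0 h group, gave 18.8%. All simulated groups had the same spread, while the real 0 h arrays correlated least within their group (0.793 to 0.929). The simulated values may therefore understate what shared 0 h arrays give, and an excess over them is not evidence of a return. Independent lists would share 3.49 risen and 0.435 fallen probe sets. With the 0 h arrays split between the contrasts the share was 13.4% on average (4.41% to 22.8% over 6 splits). The splits shared 29 to 50 risen probe sets, where independent lists would share 1.54 to 21.2, and each split lay above its own value. No simulation was run for split arrays, so what chance gives there is not known. Across probe sets, which are not independent replicates, the log2 differences had r = 0.42 against 0.528 simulated and a covariance of 0.097 against 0.0603. With split arrays the means over the 6 splits were r = -0.00582 and a covariance of -0.00748. When the tip contrast used 0 h arrays 1 and 2, both of high median, r was -0.264 and the share 4.41%. In the other splits r ran from -0.054 to 0.102. The share was 13% without tip array 1, 37.6% without stump 0 h array 2 and 15.2% without its array 4.

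At 8 dpg the tip and the stump (3 arrays each) differed in 0 probe sets by the limma test, with 238 at an unadjusted p below 0.05, 15 when only these groups entered the fit and 39 with array weights. BBM stood at 224 ± 39.5 and 279 ± 41.6 (SD), JKD at 87 ± 21.4 and 47.2 ± 26.7, and AGL42 at 215 ± 35.2 and 206 ± 42.5. In simulated data for this comparison, with changes set only in probe sets above the median, 77.6% of 4-fold and 20.9% of 2-fold changes were recovered. The 14 glutathione transferase genes had a median of -0.244 with 0 called, adjusted p = 0.0433, and adjusted p = 0.734 with an estimated correlation; with centring it was 0.06. Of the 8 auxin response genes and 5 wound and ethylene regulators 0 were called, also when adjusted over the list alone.

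Against the stump at 0 h (3 arrays against 4), the stump at 8 dpg was higher for AT1G50060 by 7.14 ± 0.583 (log2, SE; adjusted p = 1.86e-10), AT3G19430 by 6.28 ± 0.493, AT1G65570 by 5.64 ± 0.42. It was also higher for MT1C by 5.52 ± 0.814, AT1G23160 by 5.18 ± 0.48 and the endoglucanase gene GH9B6 by 4.66 ± 0.493. IAA33 (4.35 ± 0.321), scpl48 (4.33 ± 0.389), COR47 (4.28 ± 0.614) and AT1G36060 of the wound and ethylene regulators (2.67 ± 0.339) were higher. The peroxidase gene AT4G30170 (-5.05 ± 0.689), AT1G62480 (-4.41 ± 0.621), the subtilase gene SBT4.12 (-4.17 ± 0.461), AT1G04040 (-4.07 ± 0.624) and SIM (-4.05 ± 0.543) were lower. So were TUB1 (-3.72 ± 0.448), AT1G67330 (-3.64 ± 0.482) and the receptor kinase gene GSO1 (-1.58 ± 0.398). Of 51 peroxidase genes 4 were higher and 8 lower, with adjusted p = 0.012, and adjusted p = 0.748 with an estimated correlation. Of 19 mitosis and chromosome genes 3 were higher, among them the spindle checkpoint genes BUBR1 (1.76 ± 0.387) and BUB3.1 (1.61 ± 0.358). The list had adjusted p = 0.00738, and adjusted p = 0.4 with an estimated correlation. Both genes lost their calls without the 4 arrays of high median (0.824, adjusted p = 0.164, and 0.817, 0.0584). Of 11 autophagy genes 3 were higher, among them ATG8B (2.18 ± 0.469) and ATG8E (1.63 ± 0.487), with adjusted p = 0.000137, and adjusted p = 0.276 with an estimated correlation. IAA20 (1.37 ± 0.368) was the 1 of 8 auxin response genes called and AT1G36060 the 1 of 5 wound and ethylene regulators, each also 1 when adjusted over the list alone. In all 1547 probe sets changed, 828 higher and 719 lower, 53.5% higher against 77.1% with median centring, which moved the median of all probe sets from -0.174 to 0.0875. The count was 974 and 1006 without stump 8 dpg arrays 2 and 3, and 663 with only these groups in the fit. ATG8E lost its call without stump 0 h array 1 or any 8 dpg array (at most adjusted p = 0.131, log2 1.53), and GSO1 (0.0828, -1.37) and IAA20 (0.0938, 1.25) without 8 dpg array 2 or 3. IAA20 was also lost with the smaller pseudocount (0.0662), and ATG8E with the larger (0.062) and without the 4 arrays of high median (0.112). With only these groups in the fit GSO1 (0.0609), IAA20 (0.114), BUBR1 (0.11), BUB3.1 (0.0884) and ATG8B (0.0725) were lost. The larger pseudocount put GSO1 (log2 -0.752) and IAA20 (0.798) below the size threshold.

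Between the tips at 8 and 4 dpg (3 arrays against 4), AT1G65570 was higher at 8 dpg by 2.96 ± 0.42 (log2, SE; adjusted p = 0.000338), ARL by 2.57 ± 0.487, the pyruvate orthophosphate dikinase gene PPDK by 2.46 ± 0.459. So were AT3G19430 by 2.42 ± 0.493, IAA33 by 2 ± 0.321 and AT1G36060 by 1.51 ± 0.339. AT5G62330 (-1.92 ± 0.338), AT4G27450 (-1.85 ± 0.307), the methionine gamma-lyase gene MGL (-1.8 ± 0.424), AT4G15390 (-1.73 ± 0.314) and rpoA (-1.51 ± 0.354), a subunit of the plastid RNA polymerase, were lower. Nuclear photosynthesis genes had a median of -0.538 with 0 of 15 called, adjusted p = 0.0171, and adjusted p = 0.872 with an estimated correlation; with quantile normalization it was 0.12. AT1G36060 was the 1 of 5 wound and ethylene regulators called, also 1 when adjusted over the list alone. In all 101 probe sets changed, 64 higher and 37 lower, 63.4% higher against 84% with median centring. The count was 67 and 63 without tip 4 dpg arrays 1 and 3, 43, 25 and 37 without tip 8 dpg arrays 1, 2 and 3, and 220 without the 4 arrays of high median. ARL (at most adjusted p = 0.0717, log2 2.51) and PPDK (0.0679, 2.4) lost their calls without tip 8 dpg array 2. So did AT1G36060 (0.254, 1.42), AT3G19430 (0.116, 2.37), rpoA (0.328, -1.37) and MGL (0.212, -1.74), each without any 8 dpg array and without tip 4 dpg array 1 or 2, 1 or 3, 1 or 3, and 1, 2 or 3, in that order. With the smaller pseudocount AT1G65570 (0.0661), PPDK (0.112) and AT3G19430 (0.106) were lost, with the larger AT5G62330 (0.0747) and MGL (0.0797). So were, with quantile normalization MGL (0.159) and AT1G36060 (0.0536), with centring MGL (0.114), and with trend=FALSE MGL (0.0523), AT1G36060 (0.0515) and rpoA (0.063). With only these groups in the fit AT3G19430 (0.0959), rpoA (0.0871) and AT1G36060 (0.0959) were lost. Of 8 auxin response genes 0 were called, also when adjusted over the list alone.

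The tip-stump difference was itself compared between the ages as an interaction, and 43 probe sets changed, 12 higher and 31 lower at 8 dpg. SBT4.12 (3.63 ± 0.652, log2, SE, adjusted p = 0.00517), the transporter gene OCT5 (2.8 ± 0.575) and AT1G57590 (2.48 ± 0.506) had a higher signed tip-minus-stump difference at 8 than at 4 dpg. AT1G50060 (-4.78 ± 0.825), AT3G19430 (-3.86 ± 0.697), AT5G47050 (-3.8 ± 0.473), AT2G38870 (-3.69 ± 0.646), AT1G52070 (-3.14 ± 0.653) and scpl48 (-2.61 ± 0.55) had a lower one. A higher signed value need not be a wider gap, since AT1G57590 was lower in the tip than in the stump at 4 dpg. Without single arrays the count was 93, 26 and 20 (tip 4 dpg 1, 2 and 4), 93 (stump 0 h 1), 17, 27 and 18 (tip 8 dpg 1, 2 and 3) and 20, 18 and 18 (stump 8 dpg 1, 2 and 3), and without the 4 arrays of high median it was 169. OCT5 (at most adjusted p = 0.0977, log2 2.75), scpl48 (0.106, -2.57) and AT1G52070 (0.103, -3.15) lost their calls without tip 4 dpg array 2 or 4 or any array at 8 dpg, OCT5 and scpl48 also without stump 0 h array 2 and scpl48 without its array 4. AT1G57590 (0.103, 2.41) lost its call without tip 4 dpg array 3 or 4, tip 8 dpg array 1 or 2 or stump 8 dpg array 2 or 3, and with centring (0.0517). With the smaller pseudocount AT1G50060 (0.0542) and scpl48 (0.0722) were lost, with the larger OCT5 (0.113), with trend=FALSE AT1G52070 (0.0505), and without the 4 arrays of high median scpl48 (0.0688). With only these groups in the fit OCT5 (0.141), AT1G57590 (0.131), AT2G38870 (0.0664) and scpl48 (0.066) were lost. Of 8 auxin response genes and 5 wound and ethylene regulators 0 were called, also when adjusted over the list alone.

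The section, named in the design as the control that does not regenerate, was compared with the stump at 0 h (3 arrays against 4). Of 20 ribosome biogenesis genes 15 were lower in the section and 0 higher, with a median of -1.3 (log2); AT3G03920 was lower by -2.39 ± 0.283 (SE; adjusted p = 2.31e-06). The list had adjusted p = 8.46e-13, and adjusted p = 0.044 with an estimated correlation. Of 107 cytosolic ribosomal protein genes 27 were lower and 0 higher, with adjusted p = 7.71e-16, and adjusted p = 0.174 with an estimated correlation. Of 19 mitosis and chromosome genes 6 were lower, among them 3xHMG-box2 (-2.4 ± 0.369), 3xHMG-box1 (-1.92 ± 0.285) and AUR2 (-1.74 ± 0.271). The mitosis list had adjusted p = 0.00124, and adjusted p = 0.193 with an estimated correlation. Of 7 tubulin genes 5 were higher, among them TUB1 (2.14 ± 0.448), TUB6 (1.79 ± 0.368) and TUA6 (1.77 ± 0.39). The tubulin list had adjusted p = 2.22e-05, and adjusted p = 0.00229 with an estimated correlation. Of 10 xyloglucan endotransglucosylase genes 3 were higher, XTH16 (2.33 ± 0.405), XTH21 (2.33 ± 0.448) and XTH19 (2.25 ± 0.442). The list had adjusted p = 0.00319, and adjusted p = 0.227 with an estimated correlation. GAT1_2.1 (4.41 ± 0.599), AT2G20670 (4.04 ± 0.601) and the cysteine protease gene AT3G19390 (3.82 ± 0.477) were higher. So were the peroxidase genes AT3G01190 (3.74 ± 0.76) and AT4G11290 (3.22 ± 0.511), the sugar transporter gene AT3G05150 (2.94 ± 0.482), LCR68 (2.58 ± 0.54) and COR47 (2.3 ± 0.614). AT3G15240 (-3.37 ± 0.486), AT5G58784 (-3.08 ± 0.418), the lectin genes AT1G52060 (-2.96 ± 0.503) and AT1G52050 (-2.78 ± 0.486) and the pectate lyase gene AT3G53190 (-2.5 ± 0.228) were lower. Of 8 auxin response genes 1 was lower and of 5 wound and ethylene regulators 0 were called, with the same numbers when adjusted over the list alone.

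In all 2318 probe sets differed between the section and the stump, 917 higher and 1401 lower, so 39.6% were higher, against 54.6% with quantile normalization and 83.6% with median centring. The median of all probe sets was -0.228, and centring moved it to 0.179. The count was 1440 and 3478 without stump 0 h arrays 1 and 3, 1490 and 1217 without section arrays 2 and 3, and 569 with only these groups in the fit. COR47 lost its call without section array 3 (adjusted p = 0.059, log2 2.2). TUB6 (0.0622) and TUA6 (0.0648) lost theirs with only these groups in the fit, and TUA6 fell below the size threshold without the 4 arrays of high median (log2 0.947).

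**Figure D5:**
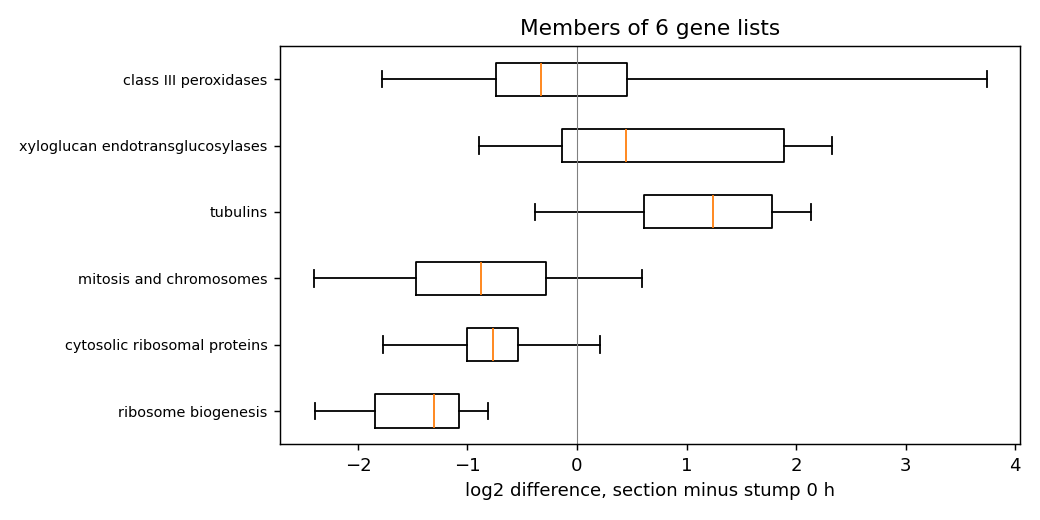
Log2 differences between the section and the stump at 0 h for the members of 6 gene lists, with boxes for the quartiles, a line for the median and whiskers to the lowest and highest member. Ribosome biogenesis genes had a median of -1.3 and tubulin genes a median of 1.24.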

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

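All the tests of explanations in this part were chosen after the results were seen. Of 110 groups of values tested for an array far from the others, over 19 genes and the array measures, 11 held one. Chance gives about 1 in 20 groups for normal values, but gene signals were tested on the linear scale, so this rate is only rough. The groups of 3 arrays (tip 8 dpg, stump 8 dpg and section) were too small for this test and were not tested.

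AT1G50060 stood at 213.1 in stump 0 h array 1, against 19.5 in the nearest other array, and this array's mean correlation with its group was 0.8108, against 0.8602. AT2G38870 stood at 406.6 in stump 0 h array 2 (nearest 75.9), and AT2G32190 at 34.5 in stump 0 h array 4 (nearest 11.9) and at 53.1 in tip 4 dpg array 1 (nearest 9). In the stump at 5 h JKD stood at 90.1 in array 1 (nearest 18.6) and AT2G42110 at 15.5 in array 4 (nearest 109.6). GAT1_2.1 stood at 200.4 in stump 13 h array 1 (nearest 29.2). In stump 22 h array 1, ALDH3F1 stood at 243.7 (nearest 57.4), AT2G42110 at 1252 (nearest 471.2) and AT3G15240 at 1526 (nearest 522.9).

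The tip-stump difference differed between 8 dpg and 4 dpg by a test of the interaction, for 43 probe sets. These included SBT4.12 (3.63), OCT5 (2.8), AT1G57590 (2.48), AT1G50060 (-4.78), AT3G19430 (-3.86), AT5G47050 (-3.8), AT2G38870 (-3.69), AT1G52070 (-3.14) and scpl48 (-2.61), on the log2 scale.

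The tip and stump arrays at 8 dpg were alike, with 0 probe sets changed by limma and 238 at an unadjusted p below 0.05. Over the 494 probe sets changed at 4 dpg, the median difference in the 4 dpg direction was 1.42 at 4 dpg and -0.0137 at 8 dpg (-0.0393 to 0.0182 without 1 array). The value of 1.42 is fixed in part by the choice of probe sets on these arrays. For differences of the 4 dpg size in these probe sets, the values at 8 dpg argue against too few arrays as the cause. Smaller or other differences are not covered, since 20.9% of 2-fold changes in brighter probe sets were recovered in simulated data. In the stump arrays at 8 dpg, 90.5% of the 274 tip-high probe sets lay nearer to the tip than to the stump at 0 h. The choice of these probe sets on the same 0 h arrays raises such shares. By another measure, 91.6% of them had a positive difference at 22 h, against a mean of 59.8% with split 0 h arrays (28.1% to 76.2% over the splits). Tip tissue in these arrays, by label or dissection, and a tip regrown after an earlier cut cannot be told apart, since both predict this share. The labels do not settle it: 192 h after the first cut is 8 days, which equals the stated age. If both values hold at harvest, a first cut after 4 days of growth is ruled out, and if either is wrong it is not.

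Rises made up 86.6% of the changes at 22 h over 0 h (76.7% to 89.5% without 1 array, a range of 12.8). With quantile normalization the share was 84% and without the 4 arrays of high median it was 75.5%, which argues against array scaling or these arrays as the whole cause. No biological explanation was tested.

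The ribosome biogenesis list was lower in the section. Its median was -1.41 with quantile normalization, which argues against array scaling as the cause, and lay at or below -1.18 against each of the other 6 groups, which argues against the stump 0 h arrays alone. A batch of the section's arrays cannot be told apart from root position: the highest correlation of a section array with another group's array was 0.9197, against at least 0.9601 within the section, as both predict. The position along the root, which the design names, stays open and untested.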

How the results depend on the processing

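Array weights, leaving out 2 or 4 arrays and the tip-minus-section score were chosen after the data were seen; the other alternatives were planned. Calls of genes are counted here by adjusted p alone. Of 197 called pairs of gene and comparison in the text, 0 changed direction under any alternative. Calls were lost for 12 with the smaller pseudocount, 11 with the larger, 7 with quantile normalization, 11 with centring, 10 with trend=FALSE, 51 with only the compared groups fitted, 7 without 2 arrays, 13 without 4 arrays and 15 with array weights; with the dimmest probe sets left out, 0 of 189 were. Over the 407 called pairs the naming rule gives, the losses were 38, 31, 44, 57, 30, 177, 33, 65 and 51, and 0 of 379. The replicate block ended 2 of the 197 calls, TUB5 (-1.12, adjusted p = 0.103) and AT1G09750 (-1.28, adjusted p = 0.0921) at 22 h, and 10 of the 407. Replicate numbers were not treated as pairs, because the labels do not say that a number marks a shared day. In deviations from the group mean, every same-numbered pair of arrays correlated above 0.1 in 0 of 28 pairs of groups. Single same-numbered pairs reached r = 0.628 (stump at 0 and 22 h), 0.337 (tip at 4 dpg and stump at 0 h) and 0.308 (tip at 4 dpg and stump at 22 h), with 2 of 4 pairs above 0.1 in each. In log2 values, stump 0 h array 1 had r = 0.913 with stump 22 h array 1 and at most 0.846 with its own group. Pairing of some arrays is therefore not excluded. With the size threshold included, 195 pairs were called, and the larger pseudocount ended 23, of which 12 by size only; leaving out 2 or 4 arrays ended 1 each by size only, and the other alternatives that keep all arrays 0. Signal over background limits the dim genes, whose log2 differences depend on the pseudocount.

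Counts of changed probe sets that moved by over 1.5 times were as follows, and their causes were not tested. With the larger pseudocount, which shrinks differences, they were 245 (tip at 4 dpg), 234 (5 h), 238 (13 h), 182 (22 h), 376 (22 h against the tip), 1 (22 h against 13 h), 797 (stump at 8 dpg) and 1008 (section). With only the compared groups fitted, the spread is estimated from these groups alone and so from fewer arrays. The counts were then 54, 139, 166, 77, 274, 0, 663 and 569 in that order. The count rose from 85 to 151 for 13 h against 5 h and from 0 to 15 for the tip against the stump at 8 dpg. The full model takes 1 spread per probe set for all groups. A group whose own spread is wider then gets SEs and p-values that are too small, and a narrower group ones that are too large. Correlations within a group were lowest at stump 0 h (0.793 to 0.929) and highest for the tip at 8 dpg (0.974 to 0.976). Whether an unequal spread between groups moved the counts was not tested. Centring gave 1 for 22 h against 13 h. For the interaction, leaving out the dimmest probe sets gave 79, the replicate block 76 and leaving out 2 arrays 125. Without 2 arrays the tips at 8 and 4 dpg gave 197. Without 4 arrays the counts were 670 (22 h), 1481 (22 h against the tip), 186 (13 h against 5 h), 220 (tips at 8 and 4 dpg) and 169 (interaction). Array weights gave 299, 295, 279 and 206 for the tip and the stump at 5, 13 and 22 h, 139 for 13 h against 5 h, 39 for the tip against the stump at 8 dpg, 375 for the tips and 276 for the interaction.

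Of 72 list calls, 5 held with an estimated correlation. Fry, whose p asks another question, called 30 lists, 24 of them among the 72 in the same direction and 6 others. The share of tip-high probe sets that rose by 22 h was 13.4% with split arrays. Under other alternatives it was 22.5% to 34.9%, and 18.9% with the replicate block. The score at 22 h was 0.0941 to 0.247 (0.107 with the replicate block), and from split arrays 0.344 to 0.524.

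Without 1 array, counts ran from 281 to 989 (tip at 4 dpg), 344 to 1078 (5 h), 328 to 842 (13 h), 213 to 549 (22 h), 497 to 1142 (22 h against the tip), 38 to 85 (13 h against 5 h), 1 to 10 (22 h against 13 h), 0 to 0 (tip against stump at 8 dpg), 25 to 110 (tips), 974 to 2306 (stump at 8 dpg), 17 to 93 (interaction) and 1217 to 3478 (section). The share ran from 13% to 37.6%, the score from 0.0513 to 0.373 and the split score from 0.219 to 0.516.

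Only uncalled values changed sign. AGL42 was -0.00399 in the tip at 4 dpg and -0.018 at 13 h with the larger pseudocount. JKD for the tips at 8 and 4 dpg was -0.00269 with the larger pseudocount and -0.0012 with the replicate block. Without 2 arrays JKD was 0.0275 (tip at 4 dpg), 0.0991 (13 h), -0.108 (22 h against the tip) and 0.154 (section). In the section JKD was 0.0663 with quantile normalization and 0.196 with centring, and BBM 0.0747 with centring. Without 1 array JKD ran from -0.628 to 0.0275 (tip at 4 dpg), -0.547 to 0.0991 (13 h), -0.446 to 0.215 (22 h), -0.108 to 0.477 (22 h against the tip), -0.21 to 0.332 (tips) and -0.492 to 0.154 (section). AGL42 ran from -0.362 to 0.532 (tip at 4 dpg), -0.28 to 0.615 (5 h), -0.437 to 0.457 (13 h) and -0.0796 to 0.181 (tip against stump at 8 dpg), and BBM from -0.555 to 0.0975 (22 h against the tip). The scan date was not run as a batch, since its fields are empty, and the split score was not run without single stump 0 h arrays or with the replicate block.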

Other observations

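All the counts of splits in this part were chosen after the results were seen. Arrays were regrouped into groups of the same sizes, with the real split included in each count.

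For the stump at 5 h against 0 h, 1 of 35 splits gave as many changed probe sets (599, highest other 94). At 13 h 1 of 35 did (450, highest other 31), as for 13 h against 5 h (85, highest other 4). In each, the highest other lay below the range of the real count without 1 array (344 to 1078, 328 to 842 and 38 to 85), which argues against chance. However, 1 of 35 is the smallest share possible and was not adjusted over the 12 comparisons, so this share alone does not exclude chance. For the tip at 8 against 4 dpg 1 of 35 gave as many (101, highest other 29), but the highest other lies within the range of the real count without 1 array, 25 to 110, so chance is not firmly excluded. The real count was 43, 25 and 37 without tip 8 dpg arrays 1, 2 and 3, and 67 and 63 without tip 4 dpg arrays 1 and 3. Fits without 1 array hold fewer arrays than the splits. Throughout this part, setting the splits against the range of such fits is therefore a rough guide and not a test. For 22 h against the tip at 4 dpg, 1 of 100 splits drawn from 126 gave as many (780, highest other 734), and the others were not run. This margin lies within the range of the real count without 1 array, 497 to 1142 (500 without tip array 3, 497 without 22 h array 3), so chance is not firmly excluded. The split with 734 moves only 22 h array 5 to the side of the tips and so keeps most of the real difference. The next highest split gave 663. For the stump at 8 dpg against 0 h (2 of 35; 1547, highest other 1869) and the section (2 of 35; 2318, highest other 2728) this count alone does not exclude chance. In both, the other split as large moves only stump 0 h array 3 to the other side and so keeps most of the real difference. Chance cannot be excluded by this count for 3 comparisons. They were the tip at 4 dpg (6 of 35 for 494, highest other 1929), 22 h against 0 h (16 of 100 for 335, highest other 2144) and 22 h against 13 h (12 of 100 for 4, highest other 213). For the interaction (7 of 100 for 43, highest other 1294) the ages were regrouped within tips and within stumps. Such a split can keep the real age difference of 1 tissue and mix the other, so this count decides nothing about chance there. The 100 splits were drawn from 126 for the 22 h comparisons and from 1225 for the interaction. For the tip at 4 dpg, 22 h against 0 h and 22 h against 13 h, a split gave several times the real count, which points to a structure of the samples other than their groups. At 4 dpg that split set tip arrays 1 and 3 with stump 0 h arrays 1 and 2 against the rest, and 3 of these are arrays of high median. The interaction's split with 1294 kept stump 8 dpg arrays 1, 2 and 3 together and mixed the tips. It therefore held the real difference between the stumps at 8 dpg and 0 h (1547 changed). For the tip against the stump at 8 dpg the 10 splits are too few for a share under 0.05 (real 0, highest other 0, all 10 as large).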
